A study of Homo sapiens with 4 samples.

How the data were processed

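RNA was measured in A549 cells, an established human lung adenocarcinoma line, after 72 h with 5 µM Complex 1, which the labels describe as a copper(I) bisphosphine complex, or with the vehicle DMSO. There were 2 libraries per group, 4 in all. Per the labels' protocols, the libraries were made from total RNA with a stranded kit that removes ribosomal RNA, and all 4 carry the same batch label. The series' design text calls the libraries of a group biological replicates.

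The authors deposited 1 table of estimated counts for 61544 Ensembl genes, with 1 column per library. The estimated counts were not scaled between libraries, and 3.69% to 3.86% of the values in a column had decimals. Per the submitters' processing notes, DRAGEN 3.9, DESeq2 and the GRCh38 genome build were used, with no role stated for any of them. The annotation release, the counting mode and the use of strand in counting are not given in the sources used here. Counts of genes with near-identical copies, such as histones, metallothioneins, ribosomal protein genes and HSPA1A, and of genes that overlap another gene are therefore uncertain. The columns of the treated libraries carry a code that the labels do not explain. They were assigned to Complex 1 replicates 1 and 2 because they were the columns not named as controls and ended in a replicate number.

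Estimated counts were rounded to whole numbers. The totals were 13564268 and 11962784 counts in vehicle replicates 1 and 2, and 14586165 and 14923047 in Complex 1 replicates 1 and 2. At these depths 1 count was worth 0.0673 to 0.0783 TMM-scaled CPM (counts scaled to a common library size), and 0 counts in a library allowed up to 0.202 to 0.235 CPM, taking 3 counts as the limit. Such limits and the counting intervals cover counting error only. Gene symbols were matched for 61445 genes from a gene name table and for 91 more from GENCODE release 29, which also gave the biotype, position and transcript GC content of 58342 genes.

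Complex 1 was compared with vehicle by edgeR 4.0.16 quasi-likelihood F tests (R 4.3.3), with TMM factors of 1.097 and 1.106 in the vehicle libraries and 0.877 and 0.941 in the Complex 1 libraries. The filterByExpr filter kept 15047 genes, and p-values were adjusted over these genes by the Benjamini-Hochberg method with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of its F statistic. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group. The median of each fixed list was the same with such genes at their bound. Where a group had 1 to 3 counts, the fold is the ratio of summed, scaled counts with an exact 95% counting interval. Replicates were compared before averaging. Chi-square per degree of freedom was 6.43 between the vehicle libraries and 16.11 between the Complex 1 libraries, so the libraries of a group differed by more than counting error. They were counted as replicates on the series' design text.

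Before the data were examined, 49 gene lists were fixed for metal, oxidative, protein folding and DNA damage stress, cell cycle, mitochondria, metabolism, inflammation, matrix, RNA classes and other cell types. The 47 lists with at least 3 tested members were tested two-sided with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists. Numbers of changed members are given over all genes tested and, where they differ, adjusted over the list alone. The rule for named genes was fixed at the same time. It takes the 8 highest and 8 lowest log2 fold changes among changed genes whose groups did not overlap, with a mean of at least 5 CPM in the higher group and no clone identifier as symbol. It always takes MT2A, MT1X, SLC30A1, SLC31A1, HMOX1, TXNRD1, HSPA1A, DDIT3, CDKN1A and FDX1. It also takes up to 3 changed members of each list past the threshold, and up to 2 of each other list, with the largest absolute log2 fold change and a mean of at least 1 CPM. Members named as exceptions within a list, and genes of the closing section, were chosen after their values were seen. Some genes that the rule takes, and some members of small counts, are not reported here.

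A further 20 settings, fixed with the lists, covered other scalings (DESeq2 size factors, library totals, upper quartile), no filter beyond 1 count, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, a test against a fold of 1.5, removal of mitochondrial and small RNA genes, a replicate block, a GC offset with and without that block, each library left out, and 3 other list tests. The scripts were tested on simulated data. In counts simulated for the comparison of Complex 1 with vehicle, with 14633 genes tested, 14% of 50 genes changed 1.25 times were called, 50% of those changed 1.5 times, 80% of those changed 2 times and 88% of those changed 4 times. Of the 124 genes called there, 8 had been left unchanged. Nearly all simulated genes were unchanged, whereas 64.4% of tested genes were called in the data. These rates therefore do not carry over to the comparison itself, and the simulation does not test the scaling. Figures were drawn with matplotlib 3.10.9.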

Results

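The experiment asked how the transcripts of A549 lung adenocarcinoma cells differ after 72 h with 5 µM Complex 1, a copper(I) bisphosphine complex, from those of cells given the vehicle DMSO. Each group had 2 libraries. Total counts ranged from 11962784 to 14923047 per library, and between 20404 and 20934 genes had a count. Pearson's r of log2 CPM across genes was 0.987 between the vehicle libraries, 0.985 between the Complex 1 libraries, and 0.877 to 0.883 between libraries of different groups. Genes are not independent replicates, so these values describe the libraries only.

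Complex 1 changed most of the measured transcriptome. Of 15047 genes tested, 9691 (64.4%) differed from vehicle, 4784 raised and 4907 lowered, and 4913 of them differed at least 2 times. CDKN1A, which encodes a cyclin-dependent kinase inhibitor, rose from 196 ± 6.1 to 2710 ± 78 CPM (mean ± SD, n = 2 libraries each), a log2 fold change of 3.79 (SE 0.13). The proliferation marker MKI67 fell from 170 ± 7.7 to 9.11 ± 1.3 CPM, a log2 fold change of -4.22 (SE 0.14). The groups did not overlap in 82.6% of tested genes, where chance gives 33.3% for 2 libraries against 2. With library totals in place of TMM factors, the median log2 fold change of all genes moved from -0.02 to -0.30, and the changed genes split into 3331 raised and 6402 lowered. With upper-quartile factors that median was -0.12.

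**Figure D1:**
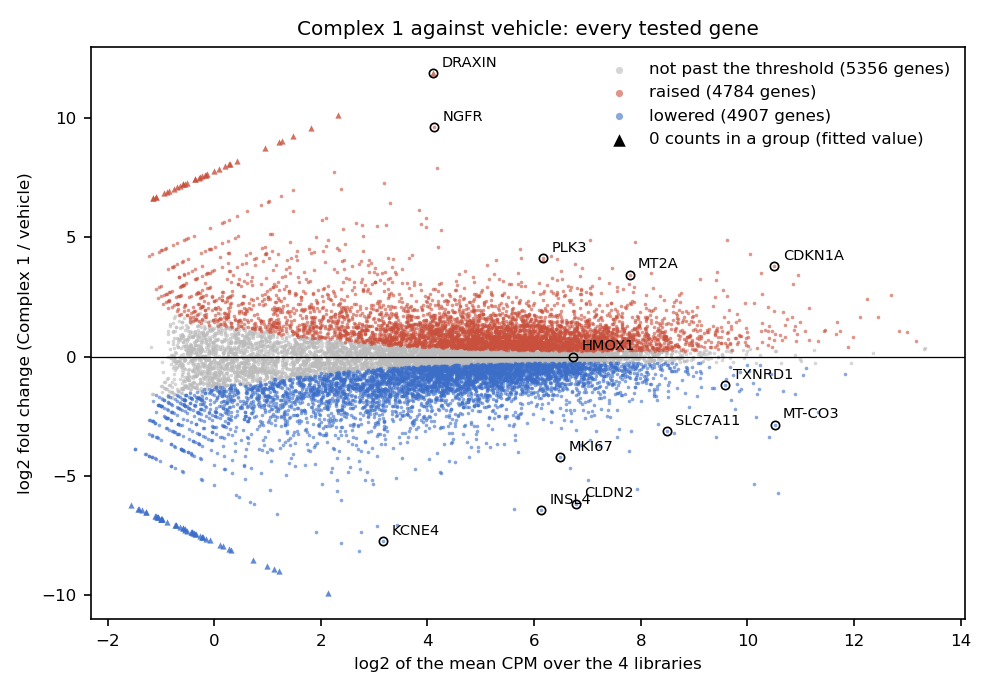
Log2 fold change of each tested gene (Complex 1 over vehicle) against the log2 of its mean CPM over the 4 libraries. Red points are the 4784 raised genes, blue points the 4907 lowered genes and grey points those not past the threshold. Triangles are genes with 0 counts in a group, drawn at fitted values that are not measured folds, and DRAXIN is among them.

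Among genes with at least 5 CPM under Complex 1 and a gene symbol, those with the highest log2 fold changes had few or no counts in vehicle. DRAXIN, which encodes a secreted axon guidance protein (chromosome 1, 11691729 to 11725857 on GRCh38), had 0 counts in vehicle and 34.4 ± 2.4 CPM with Complex 1, at least 322-fold higher. LAPTM5, encoding a lysosomal membrane protein, was at least 93.9-fold higher, and the antisense transcript UNC5B-AS1 at least 52-fold higher, with the caution that strand use in counting is not stated. NGFR, a neurotrophin receptor gene (chromosome 17, 49495293 to 49515017), had 1 count in vehicle and was 976-fold higher, with a 95% counting interval of 175 to 38600. The GABA receptor subunit gene GABRD was 266-fold higher (47.3 to 10500), the ubiquitin ligase gene MARCHF4 169-fold (57.5 to 822) and INSYN2B 146-fold (39.9 to 1210). RRAD, encoding a Ras-related GTPase, rose 237-fold, from 0.147 ± 0.11 to 35.9 ± 7.1 CPM. Its log2 fold change of 7.89 was 7.24 without control replicate 1 and 8.87 without control replicate 2. Without control replicate 2 that of NGFR moved from 9.61 to 8.83 and that of MARCHF4 from 7.28 to 7.87. Without control replicate 1 that of GABRD moved from 7.72 to 6.79 and that of INSYN2B from 7 to 6. NGFR without control replicate 1, and GABRD and INSYN2B without control replicate 2, had 0 counts left in vehicle.

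The genes below have the lowest log2 fold changes among those with at least 5 CPM in vehicle and a gene symbol. INSL4, an insulin-like peptide gene (chromosome 9, 5231419 to 5235304), fell from 139 ± 13 to 1.61 ± 0.16 CPM, 85.8-fold. F7, which encodes coagulation factor VII, fell from 21.3 ± 1.5 to 0.153 ± 0.12 CPM, a log2 fold change of -7.07 (SE 0.36) that was -8.04 without Complex 1 replicate 1 and -6.43 without Complex 1 replicate 2. For 6 others, Complex 1 left 1 to 3 counts. The alcohol dehydrogenase gene ADH6 was 353-fold lower (counting interval 63 to 14000), the villin gene VIL1 276-fold (49.1 to 10900) and C9orf152 180-fold (49.3 to 1490). The potassium channel subunit genes KCNE4 and KCNJ16 were 242-fold (66.5 to 2000) and 201-fold lower (35.6 to 7960), and PRG4, encoding the joint lubricant lubricin, 146-fold (49.8 to 713). Without Complex 1 replicate 2 the log2 fold change of ADH6 moved from -8.15 to -7.22, that of VIL1 from -7.81 to -6.88 and that of KCNJ16 from -7.33 to -6.41, and without Complex 1 replicate 1 these genes had 0 counts left with Complex 1.

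Metallothionein genes and a fixed list of metal transporter genes rose. Of 11 listed genes of metallothioneins, small metal-binding proteins, 4 passed the low-count filter. All 4 were raised (median log2 fold change 2.92, camera adjusted p = 0.0015, adjusted p = 0.55 with an estimated correlation). MT2A (chromosome 16, 56608199 to 56609497) rose 10.8-fold, from 37.5 ± 0.64 to 405 ± 100 CPM (log2 fold change 3.43, SE 0.16, edgeR adjusted p = 1.5e-09). MT1X rose 5.28-fold (2.40, SE 0.19, adjusted p = 1.7e-07). MT1A had 0 counts in vehicle and was at least 17.1-fold higher. It passed the filter only through the Complex 1 libraries, so it could only be raised. MT1F had a log2 fold change of 1.48 (adjusted p = 0.009), which was 0.82 (adjusted p = 0.17) without Complex 1 replicate 1. The list fixed as metal-responsive transporters also rose, with 6 of 6 tested members raised (median 0.64, adjusted p = 0.033, and 0.55 as the adjusted p with an estimated correlation). Its zinc exporter SLC30A1 rose 1.95-fold (log2 fold change 0.96, SE 0.10, adjusted p = 3.6e-06) and SLC41A1, a magnesium transporter, 2.47-fold. That list's adjusted p was 0.071 with library totals and 0.058 without control replicate 1. In the copper handling list 5 members rose, 4 fell and 10 did not pass (camera adjusted p = 0.43). STEAP2, a metalloreductase, fell 5.6-fold and SCO1, a copper chaperone of cytochrome c oxidase, 2.54-fold. SLC31A1, the copper importer gene, had 89.4 ± 4.6 CPM in vehicle and 80.4 ± 15 with Complex 1 (log2 fold change -0.15, SE 0.13, adjusted p = 0.31). With library totals its log2 fold change was -0.44 (adjusted p = 0.0078), and without Complex 1 replicate 1 it was -0.34 (adjusted p = 0.038).

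Genes of the p53 target list rose together. Of 30 tested members 26 were raised, TIGAR was lowered and 3 did not pass (median 1.88, camera adjusted p = 1.9e-25, adjusted p = 0.55 with an estimated correlation). Adjusted over the list alone, 26 were raised and 2 lowered. PLK3, a stress-responsive kinase gene, rose 17.4-fold (log2 fold change 4.12, SE 0.13), CDKN1A 13.9-fold and BBC3, which encodes the pro-apoptotic protein PUMA, 11.9-fold (3.57, SE 0.12). Among apoptosis regulators 14 of 26 rose and BCL2, CASP8 and CYCS fell (median 0.33, adjusted p = 0.00073, and an adjusted p of 0.55 with an estimated correlation). The raised genes BBC3, BAX, TNFRSF10A and TNFRSF10B are also in the p53 list, so the 2 calls are not separate. With library totals the median of the apoptosis list was 0.06. Raised members included genes known to promote and to restrain apoptosis. BMF, a pro-apoptotic gene, rose 24-fold and BCL2A1, an anti-apoptotic one, 11.6-fold.

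Cell division genes fell. In the mitosis list 43 of 46 members were lowered, CDC25B was raised, and BUB3 and PTTG1 did not pass (median -1.99, camera adjusted p = 8.3e-15). Besides MKI67, the spindle genes HMMR and ASPM fell 14.2-fold and 13.8-fold. Of 45 replication-dependent histone genes 36 fell, H1-3 rose and 8 did not pass (median -1.20, adjusted p = 5.7e-07). H2AC16 fell 9.8-fold and H3C12 7.9-fold, with the caution that histone genes share near-identical sequence. Among DNA repair genes 22 of 28 fell and MSH6 rose (median -0.94, adjusted p = 0.00084). XRCC2 fell 10.2-fold and the helicase gene BLM 5.33-fold. In the DNA replication list 25 of 42 fell, while CDT1, POLD1, RRM1 and TYMS rose (median -0.67, adjusted p = 0.0035). MCM10 fell 7.61-fold and MCM3 7.46-fold. Ribosome biogenesis genes fell as well, 24 of 37, with NPM1, FBL and UTP4 raised (median -0.48, adjusted p = 0.0012), and NOP58 was 3.59-fold lower. With an estimated correlation the adjusted p was 0.55 for the mitosis, histone, DNA repair and ribosome biogenesis lists and the adjusted p was 0.66 for DNA replication.

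Antioxidant genes controlled by NRF2 fell. Of 32 tested targets 20 were lowered, TKT and FTH1 were raised and 10 did not pass (median -0.48, camera adjusted p = 2.9e-06, adjusted p = 0.55 with an estimated correlation). SLC7A11, the cystine transporter gene, fell from 642 ± 13 to 74.2 ± 13 CPM (8.64-fold, log2 fold change -3.11, SE 0.13). OSGIN1 fell 5.9-fold and AKR1B10, an aldo-keto reductase gene, 5.85-fold. TXNRD1, encoding thioredoxin reductase, fell 2.28-fold (log2 fold change -1.19, SE 0.12, adjusted p = 2.1e-06). HMOX1, encoding heme oxygenase, had 74.7 and 139 CPM in the vehicle libraries and 106 and 107 CPM with Complex 1 (log2 fold change 0.00, SE 0.20, adjusted p = 1.0). Its log2 fold change was -0.39 without control replicate 1, 0.50 without control replicate 2 and -0.29 with the replicate block and GC offset.

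**Figure D2:**
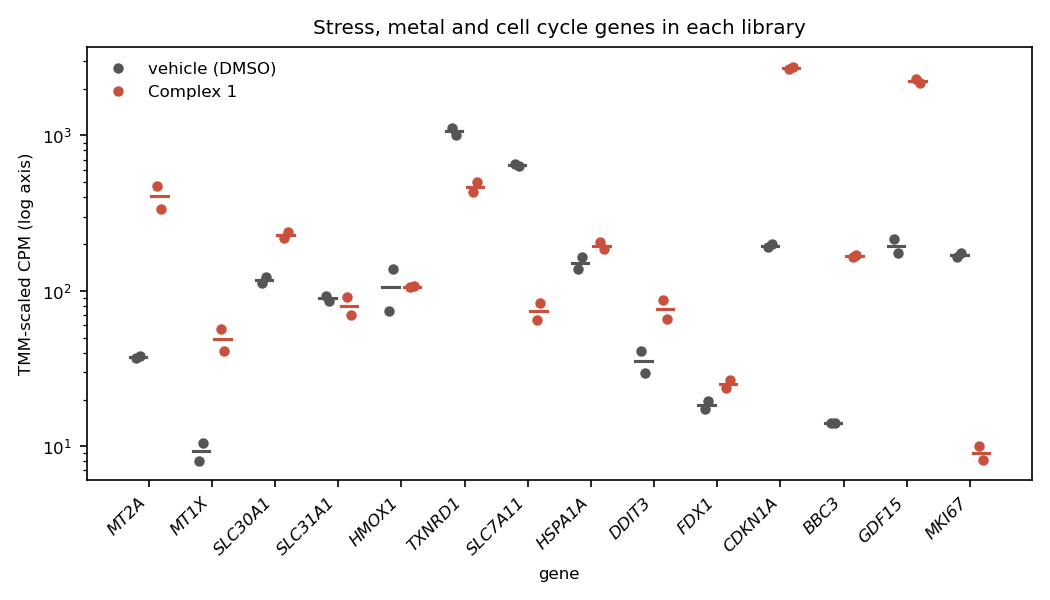
TMM-scaled CPM on a log axis for 14 genes, with a point for each of the 2 vehicle (grey) and 2 Complex 1 (red) libraries and a line at each group's mean. MT2A, CDKN1A and GDF15 lie higher with Complex 1 and SLC7A11, TXNRD1 and MKI67 lower, while the HMOX1 values of vehicle lie on both sides of those with Complex 1.

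Transcripts of the mitochondrial genome fell. They made up 2.32% ± 0.059 of counts in vehicle and 0.975% ± 0.14 with Complex 1 (SD, n = 2). Of its 13 mRNAs 12 were lowered and MT-ND1 did not pass (median -1.21, camera adjusted p = 5e-06, adjusted p = 0.63 with an estimated correlation). MT-CO3 fell 7.23-fold (log2 fold change -2.85, SE 0.15) and MT-ND5 3.58-fold. Nuclear genes for respiratory complexes II and III moved the other way, with 10 of 13 raised and SDHC, UQCRFS1 and UQCRQ not past the threshold (median 0.55, adjusted p = 0.033, adjusted p = 0.80 with an estimated correlation). UQCRC1 rose 3.04-fold and SDHA 1.8-fold. That list's adjusted p was 0.071 with library totals and 0.081 with fry, and it was 0.086 without Complex 1 replicate 1. The lists of complex I subunits (11 raised, 12 lowered of 37, adjusted p = 0.67), nuclear cytochrome c oxidase (10 raised, 2 lowered of 19, adjusted p = 0.41) and ATP synthase (2 raised, 2 lowered of 17, adjusted p = 0.96) did not pass. Adjusted over the list alone, complex I had 11 raised and 11 lowered, and ATP synthase 1 raised and 2 lowered. For ATP synthase the median was 0.06 while camera's direction was down.

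Inflammatory, matrix and cytoskeletal genes rose. In the NF-kB and cytokine list 17 of 26 rose and CXCL2, CXCL3 and PTGS2 fell (median 1.87, camera adjusted p = 7.5e-08). RELB, an NF-kB subunit gene, rose 14.5-fold (log2 fold change 3.86, SE 0.15), and CSF2, with 0 counts in vehicle, was at least 24.8-fold higher. IL1B rose from 0.185 ± 0.17 to 2.83 ± 0.13 CPM, a log2 fold change of 3.92 (SE 0.62) that was 3.18 without control replicate 1 and 5.21 without control replicate 2. Of 23 collagen, laminin and matrix genes 21 rose and COL1A1 and COL12A1 fell (median 1.48, adjusted p = 1.1e-12). COL13A1, with 0 counts in vehicle, was at least 19.9-fold higher, and COL6A3, with 1 count there, was 155-fold higher (counting interval 27.4 to 6160). The log2 fold change of COL6A3 moved from 6.96 to 6.18 without control replicate 2, and without control replicate 1 it had 0 counts left in vehicle. In the TGF-beta and mesenchymal list 17 of 23 rose and FN1 and SKIL fell (median 1.03, adjusted p = 3.2e-07). TAGLN, encoding an actin-binding protein, rose 11.4-fold and the matrix-associated gene CCN1 9.88-fold. Among actin and tubulin genes 15 of 27 rose and PFN1, TUBA1A and TUBA1B fell (median 0.38, adjusted p = 2.5e-05), and ACTG1 rose from 1880 ± 10 to 11300 ± 1400 CPM. The median of the actin and tubulin list was 0.1 with library totals and 0.23 with the GC offset, and its call stayed. Immediate early genes rose in 14 of 25 cases and fell in 6 (median 0.61, adjusted p = 0.00013), and the phosphatase gene DUSP5 rose 29.2-fold. Antigen presentation genes rose in 9 of 15 cases with none lowered (median 0.65, adjusted p = 7e-04), led by the peptide transporter gene TAP1 at 6.07-fold. For each of these 6 lists the adjusted p was 0.55 with an estimated correlation.

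**Figure D3:**
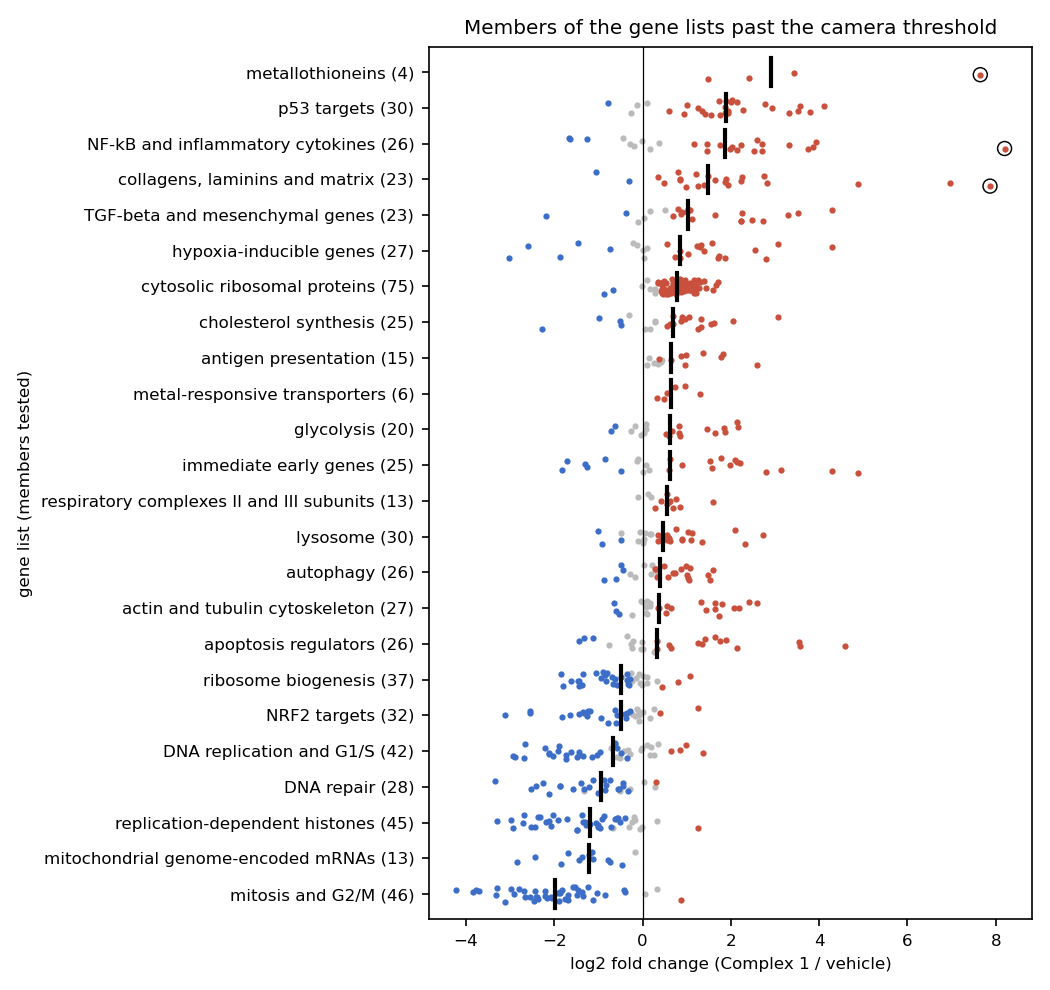
Log2 fold change of each tested member (points) and the median (black bars) of the 24 lists past the camera threshold, with the number of members tested in brackets. Red and blue points are raised and lowered members, grey points are not past the threshold, and ringed points (MT1A, CSF2, COL13A1) are fitted values of genes with 0 counts in vehicle. The medians run from -1.99 for mitosis to 2.92 for metallothioneins.

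Lists of ribosomal protein, hypoxia, metabolic and degradation genes also rose. Of 75 cytosolic ribosomal protein genes 68 rose and RPL6 and RPS26 fell (median 0.78, camera adjusted p = 3.8e-10, adjusted p = 0.77 with an estimated correlation and 0.070 with fry). Adjusted over the list alone, 69 rose. RPLP2 rose 3.25-fold and RPL39 3.16-fold. Hypoxia-inducible genes rose in 17 of 27 cases, while CA9, EGLN3, EGLN1, CA12 and HILPDA fell (median 0.85, adjusted p = 2.5e-05, adjusted p = 0.55 with an estimated correlation). CA9, a carbonic anhydrase gene, was 8.13-fold lower and LOXL2, a lysyl oxidase gene, 8.42-fold higher. Glycolysis genes rose in 12 of 20 cases, with PGK1 and SLC16A1 lowered (median 0.63, adjusted p = 0.007, adjusted p = 0.77 with an estimated correlation), and the glucose transporter gene SLC2A1 rose 3.63-fold. Cholesterol synthesis genes rose in 16 of 25 cases, with 4 lowered (median 0.69, adjusted p = 0.021, adjusted p = 0.80 with an estimated correlation and 0.091 with fry). INSIG1, which encodes a sterol-sensing regulator, rose 8.4-fold and MSMO1, an enzyme gene of the pathway, 4.14-fold. Lysosomal genes rose in 18 of 30 cases, with CTSZ, GLA and ATP6V0D1 lowered (median 0.46, adjusted p = 0.0025, adjusted p = 0.80 with an estimated correlation), and the cholesterol transporter gene NPC1 rose 6.64-fold. Autophagy genes rose in 16 of 26 cases, with MAP1LC3B, ATG4B, ATG16L1 and BECN1 lowered (median 0.40, adjusted p = 0.033, adjusted p = 0.55 with an estimated correlation). The autophagy receptor gene SQSTM1 rose 3.01-fold. The autophagy call was lost with library totals (adjusted p = 0.071) and with the GC offset (adjusted p = 0.064).

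Protein folding and lipoylation lists did not pass the camera threshold. Heat shock genes split into 12 raised and 9 lowered of 26 (median 0.11, adjusted p = 0.60). HSPA6 rose 33.6-fold from 0.395 ± 0.083 CPM and HSPB8 5.25-fold. HSPA1A, an inducible chaperone gene, had a log2 fold change of 0.37 (SE 0.11, adjusted p = 0.012) that ended with library totals (0.09, adjusted p = 0.51) and became -0.07 (adjusted p = 0.61) with the GC offset. Without control replicate 1 it was 0.24 (adjusted p = 0.21), and without Complex 1 replicate 1 it was 0.30 (adjusted p = 0.064). Endoplasmic reticulum chaperone genes had 5 raised and 10 lowered of 26 (median -0.14, adjusted p = 0.61). The ATF4 list had 12 raised and 14 lowered of 33 (median -0.11, adjusted p = 0.32). DDIT3, a stress transcription factor gene, rose 2.18-fold (log2 fold change 1.12, SE 0.16, adjusted p = 5.1e-05), and GDF15, which the p53 list also holds, rose 11.4-fold. SLC7A11, which the NRF2 and iron handling lists also hold, fell 8.64-fold. In the lipoylation and cuproptosis list 5 members rose and 7 fell of 15 (median -0.03, adjusted p = 0.56). FDX1, the ferredoxin gene, had a log2 fold change of 0.45 (SE 0.15, adjusted p = 0.017), which was 0.18 (adjusted p = 0.36) with library totals, 0.35 (adjusted p = 0.055) with upper-quartile factors, 0.35 (adjusted p = 0.14) without control replicate 1 and 0.37 (adjusted p = 0.087) without Complex 1 replicate 2.

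The remaining lists did not pass either. Selenoprotein genes had 6 raised and 9 lowered of 21 (adjusted p = 0.26), with GPX2, a glutathione peroxidase gene, 13.5-fold lower. DIO2 fell from 15.4 ± 1.3 to 0.388 ± 0.45 CPM, a log2 fold change of -5.33 (SE 0.42) that was -7.57 without Complex 1 replicate 1 and -4.42 without Complex 1 replicate 2. Iron handling genes had 7 raised and 7 lowered of 18 (adjusted p = 0.19), with the ferroxidase gene CP 25.2-fold lower. Iron-sulfur cluster genes had 9 raised and 7 lowered of 20 (adjusted p = 0.26), the tricarboxylic acid cycle 12 raised and 2 lowered of 18 (adjusted p = 0.17), mitochondrial ribosomal proteins 10 raised and 18 lowered of 53 (adjusted p = 0.26), and mitochondrial chaperones 4 raised and 5 lowered of 16 (adjusted p = 0.44). The tricarboxylic acid cycle list did pass, as higher, with no filter beyond 1 count (adjusted p = 0.015), with limma-voom (adjusted p = 0.042) and with camera on ranks (adjusted p = 0.043). Proteasome subunits had 20 raised and 8 lowered of 34 (9 lowered when adjusted over the list alone, adjusted p = 0.23), fatty acid synthesis 7 raised and 7 lowered of 18 (adjusted p = 0.93) and small nucleolar RNA host genes 6 raised and 5 lowered of 18 (adjusted p = 0.63). Interferon-stimulated genes had 15 raised and 6 lowered of 27 (median 0.75, adjusted p = 0.17), with ISG15 14.3-fold and HERC5 12.6-fold higher. Among nuclear-retained long RNAs 5 rose and TUG1 fell of 10 (adjusted p = 0.17), and NEAT1 rose from 340 ± 26 to 3630 ± 730 CPM. Despite its name, the nuclear-retained list also holds the small RNA genes RMRP, RPPH1, RN7SK, RN7SL1 and RN7SL2. It passed, as higher, without Complex 1 replicate 2 (median 0.76). The 7SL and 7SK RNA genes took 4.15% of counts in Complex 1 replicate 1, the library kept there, and 2.21% in replicate 2. That pass is therefore not read as a rise of long RNAs. The proteasome and interferon lists passed, as higher, with no filter beyond 1 count (adjusted p = 0.05 for each, under the threshold before rounding). Epithelial junction and keratin genes had 8 raised and 12 lowered of 25 (9 raised when adjusted over the list alone, median -0.27, adjusted p = 0.41), with the tight junction gene CLDN2 71.3-fold and the adhesion gene EPCAM 8.06-fold lower. Alveolar type II markers had ABCA3 raised and LPCAT1 and ETV5 lowered of 4 (2 raised when adjusted over the list alone, adjusted p = 0.69).

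Markers of other cell types had few tested members. Of 4 tested leukocyte markers LCP1 and CD68 rose (adjusted p = 0.10), LCP1 from 0.147 ± 0.11 to 3.71 ± 0.40 CPM and CD68, also a lysosomal gene, from 56.4 ± 0.31 to 203 ± 23 CPM. The log2 fold change of LCP1 moved from 4.61 to 3.96 without control replicate 1 and to 5.6 without control replicate 2. Of 5 neuroendocrine markers CHGA and ENO2, an enzyme also in the glycolysis list, rose and CHGB fell (adjusted p = 0.96, median 0.06 with camera's direction down). The fibroblast and endothelial lists had 1 tested member each and were not tested as lists. COL1A1, also in the matrix list, was 2.07-fold lower, and ESAM 4.62-fold higher at 3.17 ± 0.055 CPM with Complex 1.

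In all, camera called 24 of 47 lists, 17 higher and 7 lower, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.55. That version rests on 2 residual degrees of freedom. Camera on ranks, with the preset correlation, called 25 lists. The fry test asks whether a list changed at all, not whether it changed more than other genes, so its number of lists cannot be set against camera's. It called 24 lists, 21 of them also called by camera. It left out cholesterol synthesis, respiratory complexes II and III and cytosolic ribosomal proteins, and added iron-sulfur cluster, iron handling and leukocyte genes.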

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

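No alternative was added after the data were examined. The number of changed genes stayed between 8507 and 10046 in the alternatives that kept all 4 libraries and the null hypothesis of no change. Tested against a fold of 1.5, it was 5432, with 2629 raised and 2803 lowered, because that test asks for a larger change. Fixed lists past the threshold numbered 21 to 27, except with an estimated correlation, where there were 0 and the test rests on 2 residual degrees of freedom. Of the 9691 genes, 8480 were also called by DESeq2 and 9623 by limma-voom, each in the same direction, and 8238 with library totals. The GC offset kept 8479, 8454 of them in the same direction. Leaving out each library in turn gave 8161 to 9129 changed genes and 23 to 25 lists, with the lone library of a group assumed to vary like the other group. Of the 138 genes the rule names, 128 neither lost their call nor turned in any alternative that gave them a value. Apart from the always-named genes, they were picked as changed, with the largest fold changes, in these same libraries. Most could thus be foreseen to keep their call, and SLC31A1 had none to lose. HSPA1A had a log2 fold change of -0.07 with the GC offset and -0.07 with the replicate block and GC offset, and the cause was not tested. With the GC offset the log2 fold change of BBC3 moved from 3.57 to 2.66, that of RELB from 3.86 to 3.14 and that of OSGIN1 from -2.56 to -3.18, among others, and the calls stayed. HMOX1, which had 0.00 with all libraries, had -0.39 without control replicate 1, 0.50 without control replicate 2 and -0.29 with the replicate block and GC offset. The edgeR adjusted p of that last fit was 0.023, but the block leaves fewer than the main fit's 2 residual degrees of freedom. With block and GC offset the adjusted p of RELB was 5.3e-115, against 7.2e-11 with the GC offset alone. P-values with the block are therefore not relied on for single genes, and numbers of calls with the block carry the same limit. Robust dispersion and the test against a fold have no list result, since camera does not use them.

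No effect shared by libraries of the same replicate number was seen, though the labels do not say whether they were handled together. The difference between replicates 1 and 2 in vehicle had a correlation across genes of 0.003 with that in Complex 1. With the replicate block 9719 genes were changed and 24 lists called. That fit leaves fewer residual degrees of freedom than the main fit, so these numbers do not decide on a shared effect. Depth limits genes near 0 counts, whose folds are bounds or wide intervals.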

Other observations

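The lists of splicing factor and liver-type genes were drawn up after fold changes of many genes had been seen, though not those of the second liver-type list, and the test for liver cells was chosen after the levels it uses had been seen. Genes of splicing regulators fell with Complex 1. Of 14 SR protein genes 11 were lowered (12 when adjusted over the list alone) and SRSF4 was raised (median -1.63, camera adjusted p = 1.5e-10, adjusted p = 0.071 with an estimated correlation). SRSF6 fell from 198 to 23.5 CPM (log2 fold change -3.07, SE 0.13), SRSF5 from 138 to 20.7 CPM and SRSF1 from 213 to 35.9 CPM. Of 22 hnRNP genes, whose proteins also bind nascent RNA, 16 were lowered and HNRNPC, HNRNPF and PTBP1 were raised (median -0.79, camera adjusted p = 1.7e-06, adjusted p = 0.25 with an estimated correlation). HNRNPM had a log2 fold change of -2.57. Members of both lists had been seen to fall, so these p-values are not independent of that choice.

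Genes best known from liver were among those lowered. All 23 tested genes of the first list were lowered (median -3.58), but the list was chosen because many had fallen, so this number restates the choice. They include the fibrinogen chain genes FGA (-3.95), FGB (-5.54) and FGG (-3.70). The transcription factor gene HNF4A had a log2 fold change of -2.08. Among 11 small nuclear RNA genes 10 were lowered (median -2.50), and 472 tested antisense genes had a median of -0.59. The median was -0.4 for 461 lincRNA (long intergenic RNA) genes and 0.02 for 13032 protein-coding genes, so the fall was not particular to antisense genes. Strand use in counting is not stated, so counts of antisense genes are uncertain. The 7SL and 7SK RNA genes took 4.15% of counts in Complex 1 replicate 1 and 2.21% in replicate 2, against 2.94% and 2.85% in vehicle.

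Fold change rose with transcript GC content across 13019 protein-coding genes (Spearman's rho 0.27 across genes, which are not independent). The median log2 fold change was -0.29 in the fifth of genes with the lowest GC and 0.50 in the fifth with the highest. A GC bias that varies from library to library is argued against, since the larger slope within a group was 0.041 of the smallest slope between groups. The trend was also not the whole cause of the list calls, because 23 of the 24 called lists stayed past the threshold in the same direction with a GC offset. A bias common to both libraries of a group, or a response to Complex 1 that follows GC, stays open, since each group's libraries share their treatment.

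For the SR protein genes, the highest median over 4 scalings was -1.61. Those scalings placed the median of all genes between -0.3 and 0, so none could have removed a fall of this size. The fall does not depend on which of them is used, but the test cannot exclude a scaling error common to all 4. The GC trend is argued against as the whole cause, with a median of -1.47 under the GC offset. Nor was the fall part of a fall of the core spliceosome list as a whole, whose 38 genes had a median of -0.20 (camera adjusted p = 0.35, adjusted p = 0.75 with an estimated correlation), 11 raised and 16 lowered (17 lowered when adjusted over the list alone). Its members were split, with SNRPF at -1.68 and SNRPD1 at -1.36, but SF3A1 at 1.55 and SF3A2 at 1.35. A fall shared with some of its members stays open. A response of splicing regulator transcripts to Complex 1 stays open and was not tested.

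For the liver-type genes, liver cells mixed into the vehicle libraries are argued against. The summed CPM of 9 transcripts most abundant in hepatocytes, ALB among them and 0 of them past the low-count filter, was at most 0.0034 of the FGB level in a vehicle library. The highest median of the first list over 4 scalings was -3.56. Scalings that moved the median of all genes so little could not have removed this fall, so that test does not decide on scaling. A second list of 55 liver-type genes, whose values had not been seen, tested whether the fall extends further, and 20 of its 29 tested members fell (21 when adjusted over the list alone) and 4 rose (median -1.73, camera adjusted p = 4.2e-06 and adjusted p = 0.071 with an estimated correlation). These values are consistent with a broader loss of liver-type transcripts in A549 cells given Complex 1, which remains a hypothesis.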
